A study of Chlamydomonas reinhardtii with 4 samples.

How the data were processed

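H3K27ac ChIP-seq peak lists of 4 Chlamydomonas reinhardtii libraries were analysed: WT and dnmt1 knockout in strain CC-5155 (mt+) and in strain CC-5325 (mt−), all in the vegetative stage. Cells were fixed with formaldehyde, chromatin was sheared by sonication and precipitated with an anti-H3K27ac antibody, and size-selected amplified libraries were sequenced, per the labels' protocols. The design text of the series also names set3 strains, which are not analysed here. The submitters' processing notes name Trim Galore 0.6.7, Bowtie2 2.4.2, Picard, MACS2 2.2.7.1 and deepTools 3.5.1 without their options or order. The genome build and the peak calling options are not given in the sources used here, and the labels say that the input control was shared with an H3K4me1 data set.

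The authors deposited 1 peak list per library in narrowPeak layout, so peaks were called per library and not on pooled reads. For each peak the deposited columns give the position, a whole-number score that tracks 10 times −log10 q, the fold enrichment ratio at the summit, the −log10 p-value, the −log10 q-value and the summit. The lowest −log10 q in each list lay just above 2 (2.02, 2.09, 2.17 and 2.01). These values depend on the depth of the library and its input, neither of which the lists give, so they were used to describe, rank and filter peaks within a list, and lists were compared by overlap. The exception is the strength class of a region in the shuffles, which takes the highest −log10 q over the lists. A missing peak therefore means that no peak passed the authors' threshold, not that the mark was absent. Without read counts no model of differential enrichment was fitted. The lists held no repeated intervals, and any pair of lists had at most 2 identical intervals, so no library was a copy of another.

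Coordinates are those of the deposited lists, given from 1. The gene table at hand describes assembly v5.5. In the deposited lists 12 of the 17 chromosomes had peaks beyond the last gene of that table, by up to 3905 kb, so the builds differ and no peak was assigned to a gene. The planned counts of transcription start sites with a peak, the gene lists and the check of the DNMT1 gene were left out for that reason.

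A peak was called lost in dnmt1 when a WT peak overlapped no dnmt1 peak of the same strain by at least 1 bp, and gained in the reverse case. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only and treat peaks as independent. Overlapping peaks of all 4 lists were merged into regions, and each region was classed by the libraries with a peak. Regions held by both WT or both dnmt1 libraries alone have the genotype pattern, those held by both libraries of a mating type the mating type pattern, and the other pairs the crossed pattern. Sharing between strains was set beside the product of the list sizes over all regions and beside 1000 shuffles within 10 classes of peak strength (the highest −log10 q of the region, or as an alternative its highest percentile within a list). The mating type locus was taken as the sequence named mating_type_plus and as chromosome 6 from 300 to 800 kb, and compared with windows of the same length tiled over the chromosomes, from 300 kb of each for the chromosome 6 window. The chromosome 6 window follows the approximate position of the locus in mt+ assemblies. The borders of the locus in the build of the lists were not located. The regions named in the text are, by a rule fixed before the data were examined, the 10 gained and 10 lost in both strains, the 5 gained and 5 lost per strain, and the 10 per direction of the mating type pattern with the highest fold enrichment (the lower of both libraries for regions held by a pair). The count of each direction of a pattern taken separately, the blocks, and the regions of chromosome 5 and mating_type_plus outside these lists were chosen after their values were seen.

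Alternatives were an overlap of at least 50% of the shorter peak, summits within 200 bp, a −log10 q of at least 10, lists cut to the shortest list's length, peaks above the median −log10 q of their list only, a window of 200 to 1000 kb on chromosome 6, and numbered chromosomes only. On simulated data made from the 14990 peaks of the WT mt+ list, with 200 regions lost and 200 gained in both knockouts, 200 gained and 202 lost regions were called. Both simulated WT lists were that same list with slightly shifted edges, and new peaks lay in the middle of wide gaps. No peak dropped out between the WT lists, so the run checks the counting and not the error on the real lists. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.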

Results

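H3K27ac, acetylation of histone H3 at a lysine that marks active promoters and enhancers, was profiled by ChIP-seq in vegetative cells of the unicellular green alga Chlamydomonas reinhardtii. The 4 libraries formed a crossed design of genotype and mating type with 1 library per group. Wild type (WT) and a knockout of DNMT1, an enzyme of the cytosine DNA methyltransferase family, were each profiled in strain CC-5155, of mating type plus (mt+), and in strain CC-5325, of mating type minus (mt−). Strain and mating type changed together, so a difference between mt+ and mt− libraries is also a difference between those strains. The series title names DNA methylation and meiotic recombination at the sex-determining region as the wider subject, and these libraries address where H3K27ac peaks differ with DNMT1 and with mating type. With 1 library per group no difference between conditions was tested, and every comparison below describes these libraries.

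The peak lists were of similar size. WT mt+ had 14990 peaks over 13.03 Mb, WT mt− had 15065 over 13.22 Mb, dnmt1 mt+ had 14986 over 12.93 Mb and dnmt1 mt− had 15323 over 13.42 Mb. Median peak width ran from 805 to 826 bp and the median of the authors' fold enrichment per peak from 5.39 to 5.83. Read depth is unknown, because the lists give no counts. Merging overlapping peaks of all lists gave 15521 regions, of which 14364 (92.5%) had a peak in all 4 libraries. Another 325 regions had a peak in 3 libraries, 439 in 2 and 393 in 1.

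The dnmt1 libraries of both strains shared H3K27ac peaks that neither WT library had, most of them in the lower part of the lists but some strong, whereas the peaks missing from both knockouts were few and weak. In all, 166 regions had a peak in both dnmt1 libraries and in neither WT library. Only 41 regions had the opposite pattern. The crossed pairings, which no factor of the design predicts, held 57 regions (WT mt+ with dnmt1 mt−) and 19 regions (WT mt− with dnmt1 mt+). The 19 were not scattered evenly, as 7 lay within 50 kb of a chromosome end. On numbered chromosomes 231 of 14235 regions shared by all 4 libraries and 11 of 160 gained regions did so. Gained regions had a median fold enrichment of 3.10 in dnmt1 mt+ (interquartile range 2.24 to 4.85) and of 3.32 in dnmt1 mt− (2.24 to 5.13). Lost regions had medians of 2.18 in WT mt+ and 1.93 in WT mt−. Of the 166 gained regions, 22 ranked above the median −log10 q of both dnmt1 lists, while 0 of the 41 lost regions did so in the WT lists. In the dnmt1 mt+ list the median gained region ranked at the 19.1th percentile of −log10 q, and 122 of the 166 had a −log10 q of at least 10 in both dnmt1 libraries. With summits required to lie within 200 bp, 268 regions were gained and 150 lost, and with lists of equal length 151 were gained and 70 lost, while the crossed pairings then held 35 and 39.

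**Figure D1:**
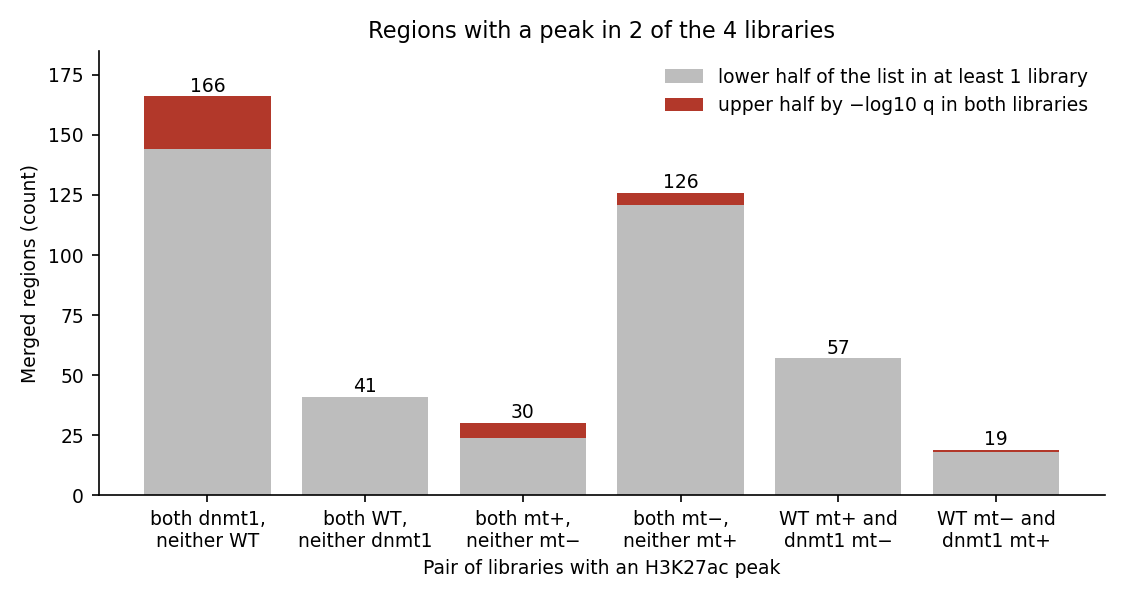
Count of merged regions (y axis) for each pair of libraries that alone held a peak (x axis), with 1 library per group. Red marks regions above the median −log10 q of the list in both libraries and grey the others; 166 regions were held by the dnmt1 pair, against 41 by the WT pair and 57 and 19 by the crossed pairs.

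The gained regions with the highest enrichment lay on 9 different chromosomes. The first was at chromosome 6, 4566839 to 4567886, with a fold enrichment of 7.94 in dnmt1 mt+ and 8.26 in dnmt1 mt−, which placed it at the 97th percentile of −log10 q in each list. The region at chromosome 1, 1084711 to 1085748, had 7.11 and 7.75, and the one at chromosome 7, 3097037 to 3098083, had 7.61 and 7.09. Next came chromosome 10, 3631213 to 3632453 (7.03 and 7.23), chromosome 14, 2264868 to 2265871 (6.64 and 7.13), and chromosome 17, 6274303 to 6275462 (7.71 and 6.63). The list closed with chromosome 3, 6978559 to 6980092 (6.61 and 8.09), chromosome 16, 3442464 to 3443311 (6.18 and 6.78), and 2 regions of chromosome 12, at 6656322 to 6657040 (6.07 and 6.14) and at 1624 to 2472 (6.59 and 5.96).

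The lost regions with the highest enrichment were narrower. The first was at chromosome 15, 1984188 to 1984711, with a fold enrichment of 3.11 in WT mt+ and 3.82 in WT mt−, and a lost neighbour lay at 1987760 to 1988163 (2.26 and 2.67). Another region of that chromosome, at 2743028 to 2743293, had 2.30 and 2.24. A pair was on chromosome 11, at 2898541 to 2898986 (2.75 and 2.24) and at 467752 to 468021 (2.64 and 2.19). The others were at chromosome 12, 2721097 to 2721712 (2.43 and 2.34), chromosome 8, 3192941 to 3193286 (2.71 and 2.22), chromosome 4, 2131895 to 2132209 (2.30 and 2.21), chromosome 6, 1382664 to 1382968 (2.62 and 2.15), and contig 38, 25556 to 25925 (2.33 and 2.37).

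Gained regions were found on every one of the 17 chromosomes but not evenly. Chromosome 12 had 17, chromosome 15 had 16, chromosome 3 had 15 and chromosome 17 had 13, whereas chromosome 2 had 2 and chromosome 14 had 1. As a share of all regions of a chromosome, chromosomes 15 (2.74%), 5 (2.37%) and 4 (1.95%) led. Chromosomes 12 (1.16%) and 3 (1.12%) had lower shares, and chromosomes 14 (0.187%) and 2 (0.165%) the lowest. A further 6 lay on unplaced contigs. Many fell in dense blocks, 73.5% having another gained region within 50 kb. The 15 on chromosome 3 all lay between 6978559 and 7161691, and the 12 on chromosome 10 all lay between 3597926 and 3741540. Those of chromosomes 15 and 12 were more spread, with 5 of 16 and 8 of 17 in the densest 200 kb. Blocks of 9 were found on chromosome 4 (852259 to 934219), chromosome 7 (3056919 to 3194365) and chromosome 9 (4251642 to 4358436), and a block of 8 regions, with fold enrichments of 1.51 to 2.35, lay on chromosome 5 (3629532 to 3652057). The chromosome 5 block had a median spacing of 2198 bp and held 8 of the 11 gained regions of that chromosome, so weak peaks make up most of its share. Regions shared by all 4 libraries numbered 3, 1, 6, 7, 1 and 0 in the blocks of chromosomes 3, 10, 4, 7, 9 and 5.

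**Figure D2:**
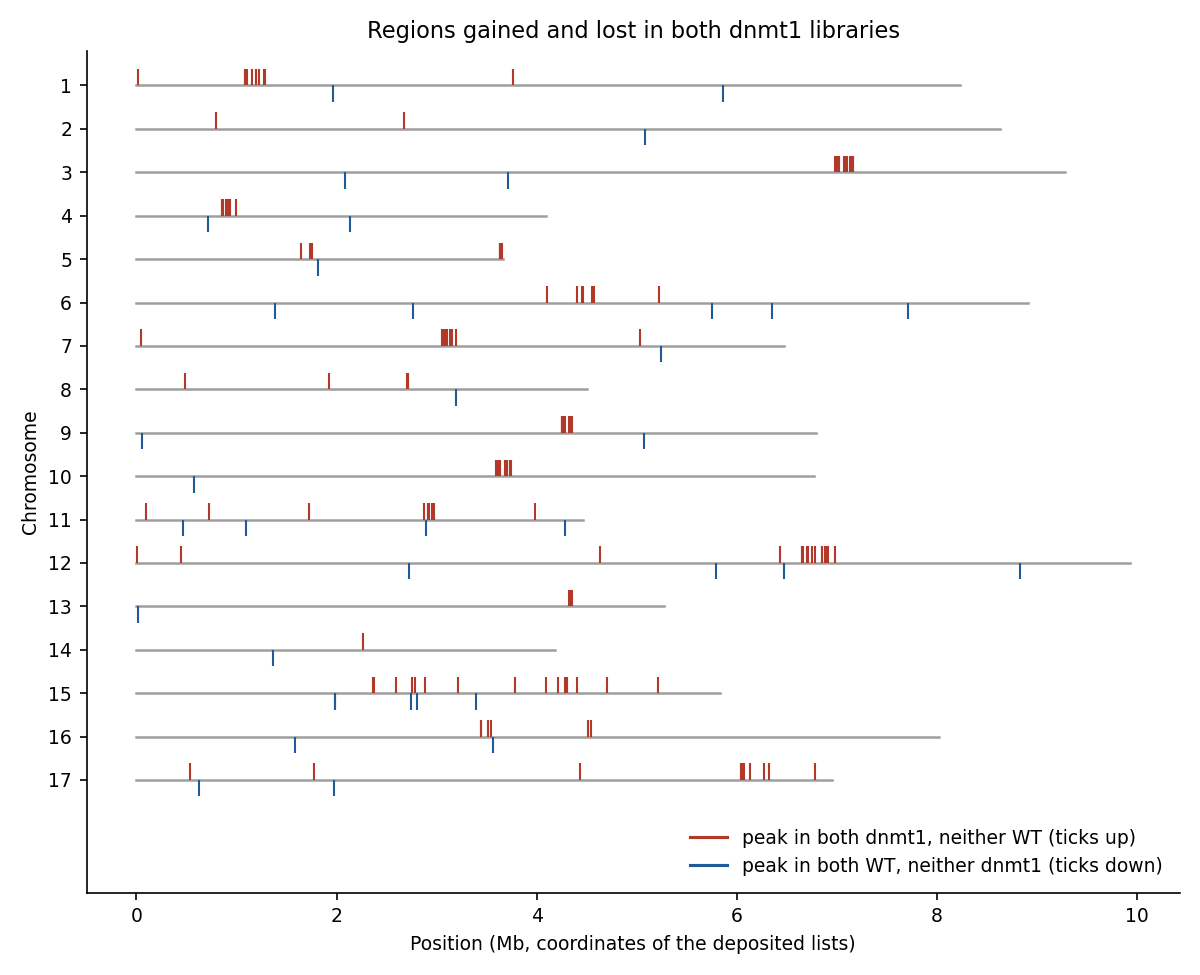
Position in Mb (x axis) of regions gained (red, up; 166 in all, 160 on numbered chromosomes) and lost (blue, down; 41 in all, 37 on numbered chromosomes) in both dnmt1 libraries, for each chromosome (y axis). Grey lines end at the last deposited peak; the 15 gained regions of chromosome 3 and the 12 of chromosome 10 each form a single block.

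**Figure D3:**
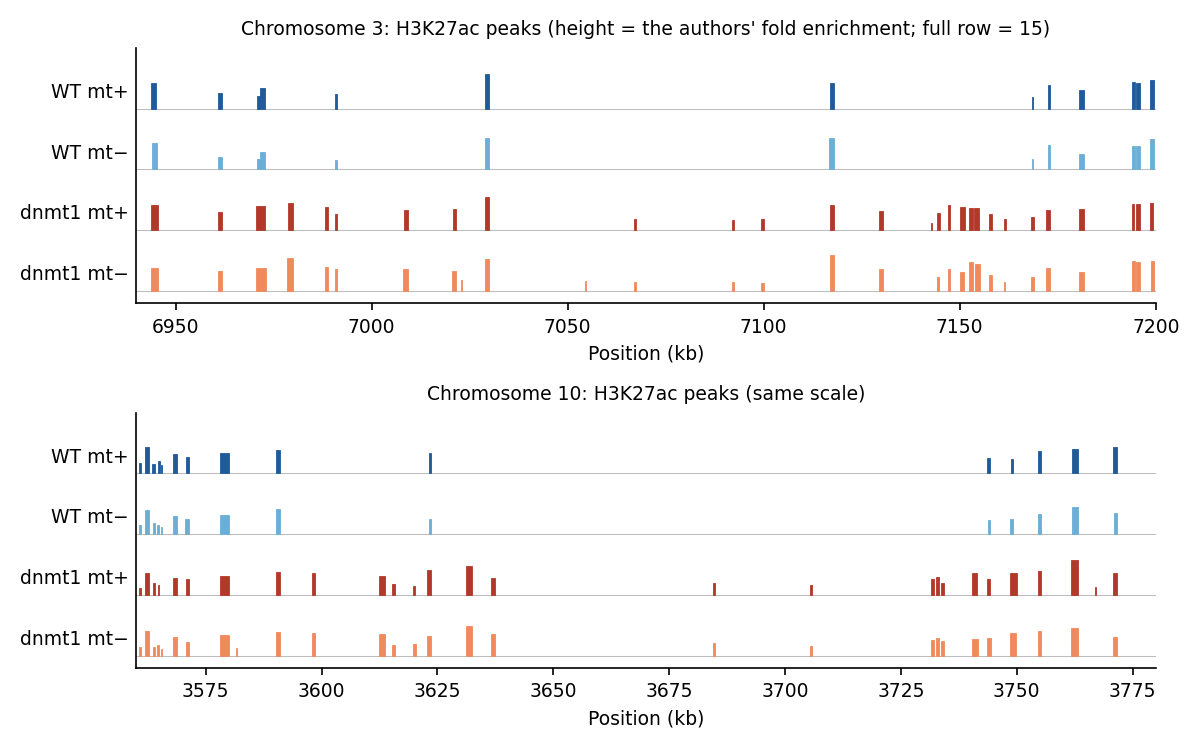
Deposited peaks of the 4 libraries (rows) along 2 blocks of chromosomes 3 and 10 (x axis in kb); bar height is the authors' fold enrichment of each peak, on the scale given in the panel titles. Both dnmt1 rows hold peaks where the WT rows have none.

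Within strain CC-5155 (mt+), 299 of the 14986 dnmt1 peaks had no overlapping WT peak (2.0%, exact 95% binomial interval 1.78 to 2.23, counting error only), and 356 of the 14990 WT peaks had no overlapping dnmt1 peak (2.37%, 2.14 to 2.63). The 5 gained peaks with the highest fold enrichment all had a partner in dnmt1 mt− and none in WT mt−. They were the regions of chromosomes 6, 17, 7 and 1 named above, with 7.94, 7.71, 7.61 and 7.11, and a peak at chromosome 13, 4323966 to 4325228, with 7.41. The 5 lost peaks with the highest fold enrichment, on chromosomes 3, 6, 7 and 17, ranged from 4.16 to 5.07, and each had a partner in dnmt1 mt−. WT mt− had no peak at chromosome 3, 3413197 to 3413642, or at chromosome 7, 4956504 to 4957085. These regions had 4.53 and 2.07 in dnmt1 mt−, so they were of the crossed pattern. Of the gained peaks 33 ranked above the median of the dnmt1 mt+ list, against 0 of the lost peaks in the WT mt+ list, and 30 of those 33 were also gained in the mt− strain.

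Within strain CC-5325 (mt−), 455 of the 15323 dnmt1 peaks were gained (2.97%, exact interval 2.71 to 3.25) and 209 of the 15065 WT peaks were lost (1.39%, 1.21 to 1.59). The 5 gained peaks with the highest fold enrichment included the regions of chromosomes 6, 3, 1 and 10 named above, with 8.26, 8.09, 7.75 and 7.23. The fifth, at chromosome 6, 4538540 to 4539673, had 7.70 and also had a peak in WT mt+. The lost peaks with the highest fold enrichment were at chromosome 17, 4536957 to 4537444 (6.74), chromosome 7, 107439 to 108265 (6.42), chromosome 17, 5246099 to 5247196 (5.93), chromosome 15, 1996961 to 1997552 (5.0) and chromosome 17, 4547426 to 4547842 (4.54). Of these, all but the chromosome 15 peak had a partner in dnmt1 mt+. WT mt+ had no peak at the chromosome 7 and chromosome 15 regions. Of the gained peaks 30 ranked above the median of their list, 27 of them gained in the mt+ strain too, and 3 lost peaks did so, of which 0 were lost in the mt+ strain. With lists of equal length, which holds gains and losses near each other by construction, 324 peaks were gained and 334 lost.

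The comparisons in the 2 strains shared no ChIP library, so their overlap can be set against chance. Gains concerned 283 regions in the mt+ strain and 451 in the mt− strain, and 166 were common to both. Independent lists would share 8.22, and 1000 shuffles within 10 classes of peak strength shared 33.1 on average, with a 95% range of 24 to 42 and a highest value of 47. Losses concerned 346 and 204 regions with 41 in common, against 4.55 for independent lists and 28 to 47 for the strength-matched shuffles. The overlap of gains thus lay above all matched shuffles and that of losses within their range. With lists of equal length the overlaps were 151 gains (shuffles 14 to 30) and 70 losses (51 to 75), but with summits within 200 bp both lay above their shuffles, at 268 gains (67 to 96) and 150 losses (57 to 85). The labels state that the input control was shared with another data set without saying which libraries used which input, so a control common to the strains is not excluded. The shuffles treat regions as independent, although gained regions lay in blocks.

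Mating type was marked by peaks on chromosome 6 and on the separate sequence that the lists call mating_type_plus. Regions with a peak in both mt+ libraries and in neither mt− library numbered 30, of which 15 lay on mating_type_plus and 4 on chromosome 6. The opposite pattern held 126 regions, of which 68 lay on chromosome 6. With lists of equal length these counts were 51 and 85. The mating_type_plus sequence had 26 peaks in WT mt+ and 22 in dnmt1 mt+, against 8 in each mt− library. The mt− peaks there were at 7 regions common to all 4 libraries and 1 further region.

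All 10 mt+ only regions with the highest enrichment were on mating_type_plus. The leading one, at 124792 to 125765, had a fold enrichment of 7.51 in WT mt+ and 7.77 in dnmt1 mt+. It was followed by 131650 to 132514 (7.06 and 6.91), 146585 to 147824 (6.17 and 6.32), 161302 to 161869 (6.32 and 5.95) and 364723 to 365338 (5.68 and 5.73). The remaining 5 ranged from 4.28 to 6.55. All 10 mt− only regions with the highest enrichment were on chromosome 6. The leading one, at 583119 to 584265, had 7.75 in WT mt− and 10.3 in dnmt1 mt−. Others were at 604480 to 605641 (6.65 in both), 579561 to 581209 (6.24 and 8.29), 640069 to 641095 (5.49 and 7.18), 629366 to 630458 (5.90 and 6.17), and, farther along the chromosome, 1312374 to 1313362 (6.89 and 6.06).

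The chromosome 6 window from 300 to 800 kb held 77 peaks in WT mt+, 69 in dnmt1 mt+, 104 in WT mt− and 110 in dnmt1 mt−. It had 26 mt− only regions, against at most 7 in 203 other windows of the same length tiled from 300 kb of each chromosome. This tiling leaves out the start of chromosome 6, where 27 mt− only regions lay between 157729 and 258379. Within the WT pair, 251 mt+ peaks had no mt− partner (1.67%, exact interval 1.48 to 1.89) and 325 mt− peaks had no mt+ partner (2.16%, 1.93 to 2.4). Within the dnmt1 pair the counts were 124 (0.827%, 0.689 to 0.986) and 514 (3.35%, 3.07 to 3.65), and with lists of equal length they were 257 and 312. Leaving out chromosome 6 and mating_type_plus left 69 of the 156 regions with a mating type pattern.

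**Figure D4:**
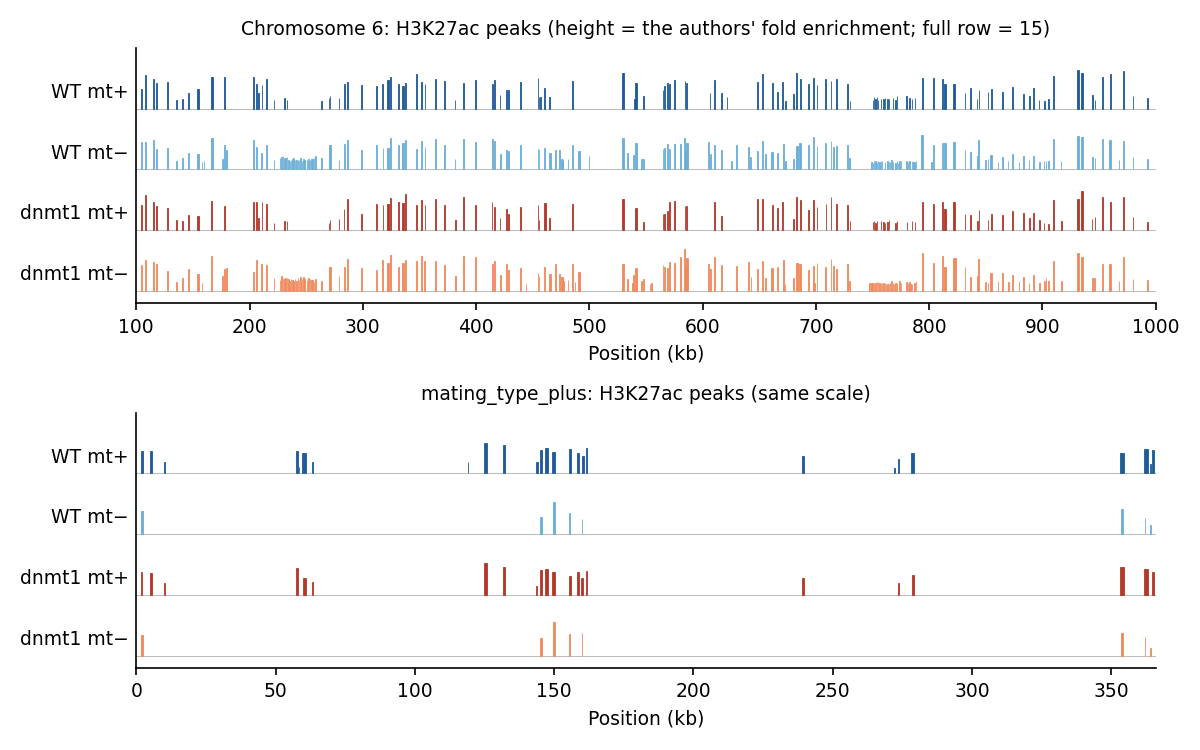
Deposited peaks of the 4 libraries (rows) along chromosome 6 from 100 to 1000 kb and along mating_type_plus (x axes in kb); bar height is the authors' fold enrichment of each peak. The mt− rows hold peaks on chromosome 6 that the mt+ rows lack, and mating_type_plus has 26 and 22 peaks in the mt+ rows against 8 in each mt− row.

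In the stretches taken as the mating type locus, no region was gained in both strains. Where reads of 1 strain do not align, such a gain cannot be seen. The lists do not show where that holds, so this count says little about the effect of the knockout there. On mating_type_plus, 0 of the 26 regions were gained in dnmt1 mt+ and 4 were lost. The lost ones were weak, at 58333 to 58593 (fold enrichment 1.69), 118924 to 119146 (2.93), 272073 to 272312 (1.38) and 363936 to 364309 (2.34 in WT mt+). Of the 18 WT mt+ peaks there without a partner in WT mt−, 15 had a peak in dnmt1 mt+ as well. In the chromosome 6 window from 300 to 800 kb, with 116 regions, 0 were gained in both strains. In the mt+ strain 0 were gained and 8 lost, and in the mt− strain 10 were gained and 4 lost. Over all 15521 regions, 283 were gained and 346 lost in the mt+ strain, and 451 gained and 204 lost in the mt− strain. The window's shares were thus higher than those over all regions, except for gains in the mt+ strain. These counts are small and the difference was not tested. A count of 0 was common elsewhere: 162 of the 203 other windows also had 0 regions gained in both strains.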

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

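The test of weak peaks in this part was chosen after the result was seen. Gained minus lost peaks in dnmt1 went in opposite directions in the strains, at -57 in the mt+ strain and 246 in the mt− strain; the difference was not tested. Weaker peaks are a candidate explanation: among peaks above the median −log10 q of their list, gained minus lost was 33 in the mt+ strain and 27 in the mt− strain. The opposite signs came from peaks below the median (-90 and 219). Of the stronger gains, 30 of 33 and 27 of 30 were gained in the other strain too, so their common sign largely restates the shared gains. With a −log10 q of at least 10 in every list the signs stayed opposite. There were then 287 gained and 420 lost peaks in the mt+ strain, and 428 gained and 228 lost in the mt− strain. This cut was applied to every list, so it moves the threshold to 10, and peaks near 10 can then count as lost or gained. The unchanged signs thus cannot show whether peaks near a threshold set them. The dnmt1 mt− list was also the longest, with 15323 peaks against 14986 for dnmt1 mt+. With lists of equal length, 324 peaks were gained and 334 lost in the mt− strain, but equal lengths hold the difference near 0 by construction and so do not test its sign. A real difference between the strains among weak peaks stays open, since each has 1 library.

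The dnmt1 mt− list had 3 peaks on the mitochondrial sequence, at 797 to 1186, 3400 to 4084 and 15425 to 15656, with fold enrichments of 1.23, 1.28 and 1.52, whereas the other lists had 0.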

How the results depend on the processing

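The alternatives for each direction of a pattern taken separately, those of the shuffles, and those without chromosome 6 and mating_type_plus or on numbered chromosomes for the region patterns were chosen after the results were seen, and the 1 kb rule after the main counts but before its own values. Of 122 alternative values for 33 results, 74 stayed within 1.5 times the main value, including all those with an overlap of at least 50% of the shorter peak, with numbered chromosomes only, and with a −log10 q of at least 10 except the regions of WT mt− with dnmt1 mt+ (30). Requiring summits within 200 bp, which parts broad peaks that overlap, raised the counts: 1036 lost and 1032 gained peaks in the mt+ strain, 1035 lost and 1293 gained in the mt− strain, 968 and 1042 unpartnered peaks of WT mt+ and WT mt−, 880 and 1217 of dnmt1 mt+ and dnmt1 mt−. The regions rose to 418 for genotype (268 gained, 150 lost), 322 for mating type (113 mt+ only, 209 mt− only) and 262 for the crossed pattern (144 of WT mt+ with dnmt1 mt−, 118 of WT mt− with dnmt1 mt+). Counting only peaks above the median −log10 q of their list left 0 lost and 33 gained in the mt+ strain, 3 lost and 30 gained in the mt− strain, 6 and 7 unpartnered in the WT pair and 11 and 8 in the dnmt1 pair, and 22 genotype (22 gained, 0 lost), 11 mating type (6 mt+ only, 5 mt− only) and 1 crossed region (0 of WT mt+ with dnmt1 mt−). With every list at the shortest list's length, 334 peaks were lost in the mt− strain, 257 and 312 were unpartnered in the dnmt1 pair, and 70 regions were lost in both strains, while 151 were gained, 35 and 39 crossed, 51 mt+ only and 85 mt− only; near-equal gains and losses within a strain then follow from the equal lengths. The chromosome 6 window from 200 to 1000 kb held 120, 177, 112 and 182 peaks in WT mt+, WT mt−, dnmt1 mt+ and dnmt1 mt−. Leaving out chromosome 6 and mating_type_plus left 69 mating type regions, and requiring no WT peak within 1 kb of the gained ones and no dnmt1 peak within 1 kb of the lost ones left 149 gained and 27 lost. The overlap of gains between strains lay above all shuffles under each alternative run. That of losses lay within the 95% range except with summits within 200 bp, where the cause was not tested. Results of transcription start sites were not run, for lack of an annotation of the same build. Genotypes were compared within each strain; no replicate could be left out, as each group has 1 library. Read depth is unknown, so what it limits was not measured; 625 to 725 peaks per list had a −log10 q under 10.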

Other observations

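Of the tests in this part, those of shifted peak edges (the 1 kb rule) and of peak-poor chromatin over all regions were chosen after the 166 regions had been counted but before their own results were seen. The tests of list length, a shared chromosome segment, weak peaks (rank and shuffles), neighbouring gains, peak-poor chromatin with each block counted once, absent sequence and hidden peaks, and the choice of the spaced groups, the densest 200 kb and gaps over 50 kb, came after the result was seen.

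Some peaks were regularly spaced, and the following examples were not drawn from a search of all regions. On chromosome 6 from 226905 to 258379, 24 of the 26 regions were mt− only, with fold enrichments of 1.93 to 3.57 in WT mt− and dnmt1 mt−. The median spacing of these 24 was 1.21 kb (range 1.13 to 2.4 kb). At the start of chromosome 15, from 9343 to 61940, 5 of the 9 regions were present in WT mt− and dnmt1 mt+ but not in WT mt+ and dnmt1 mt−. These 5 had fold enrichments of 2.5 to 3.26 and spacings of 12.8 to 12.9 kb.

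Of the gained regions on numbered chromosomes, 115 of 160 (71.9%) lay in the densest 200 kb of their chromosome, against 20 to 25% for random shared regions, and 13 chromosomes had at least 4 in that stretch. In gaps of over 50 kb between WT peaks, which held 3.87% of the gap length, lay 62 of the 158 gained regions with a measurable gap. Positions of centromeres, repeats or methylated domains in the build used were not analysed here.

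The 166 regions with a peak in both dnmt1 libraries and neither WT library were set against technical explanations. Longer dnmt1 lists were argued against by lists of equal length, where these regions were 4.08 times the mean of the crossed directions. The dnmt1 mt+ list was already the shortest, so this bears on dnmt1 mt−, and equal lengths do not test sensitivity. A single chromosome segment shared by both mutants was argued against by the most loaded chromosome holding 10.2% of the 166 regions. That share cannot address several shared segments on different chromosomes. Shifted edges were argued against by 89.8% of the regions having no WT peak within 1 kb. For weak peaks crossing the caller's threshold, the first test, of the median rank in the dnmt1 mt+ list, gave the 19.1th percentile, between its bounds of 10 and 20, and decided nothing; a second, written after that outcome, counted 166 regions against at most 47 in strength-matched shuffles, which argues against weak peaks as the whole cause but leaves the weaker regions open one by one. One hypothesis is that peak-poor chromatin may gain the mark without DNMT1. The WT peak-free gaps holding these regions had a median length of 28.5 kb, which counts members of a block separately. With 1 region drawn from each of 59 blocks or lone regions the median was 19.8 kb, against 7.7 to 12.1 kb for as many random positions. Of the 166 regions, 73.5% had another such region within 50 kb, against 7.23 to 21.1% of random shared regions. Regions held by 1 dnmt1 library alone did not lie in longer gaps than random positions. Their median gaps were 11.03 kb for 145 regions of dnmt1 mt− and 8.75 kb for 34 of dnmt1 mt+. Both fell within the range for 158 random positions (8.35 to 11.08 kb), the first near its upper bound. Other regions gained in 1 strain only had a peak in the other strain's WT library and were not in this comparison. The hypothesis was thus not extended beyond regions gained in both strains. Several chromosome segments shared by both mutants, reads aligned to several repeat copies, a shared input and copy number stay open, as none was tested.

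For the mt− only peaks on chromosome 6, DNA methylation by DNMT1 hiding them in mt+ cells was argued against: of 62 regions from 200 to 1000 kb with a peak in WT mt− and not in WT mt+, 1.61% (1 region) had a peak in dnmt1 mt+, and of 30 such regions from 300 to 800 kb 0 did. Sequence that the mt+ strain lacks, or that differs too far for its reads to align, is a candidate explanation, as the mirror image of 15 mt+ only regions was found on mating_type_plus. A difference in the mark on sequence present in both strains stays open, because the lists do not show which sequences each strain carries.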
